A study of Mus musculus with 6 samples.

How the data were processed

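RNA was measured in cultures of Melan-a, an immortal line of pigmented mouse melanocytes from the C57BL/6 strain. Per the labels' protocols, cells were transfected with a small interfering RNA against Dicer (siDicer) or with a control siRNA (siScr), and lysed 24 hours later. Total RNA was labelled with the WT PLUS chemistry and hybridised to mouse Clariom D arrays, which carry probe sets for coding and noncoding transcripts. There were 6 arrays, 3 per group, described by the submitters as biological replicates. RNA integrity numbers ran from 9.7 to 10, per the labels.

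The deposited values are log2 signals per probe set, made by the authors with Affymetrix Expression Console per the submitters' processing notes. The version, background correction and normalization method are not given in the sources used here. The array medians lay between 4.58 and 4.64 and the quartiles were nearly equal, as in values scaled between arrays before deposit. No value was changed or filtered out for the results reported first. Normalization that equalises arrays would hide a change shared by most transcripts, and log2 differences between dim probe sets are compressed by background signal.

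The table held 16383 probe sets, each a transcript cluster. A gene symbol from the platform annotation was attached to 7530 of them, 455 carried several symbols and 8398 none. Symbols of 230 probe sets were brought up to date through their Entrez numbers, and 7486 genes had a probe set of their own. Of the named probe sets, 7439 lay on chromosomes 1 to 4 in the RefSeq gene table, 9 on another chromosome and 82 had no place in it. Results for named genes are therefore almost only about chromosomes 1 to 4, and counts are not those of a whole transcriptome. Dicer1 and Mitf were not analysed here, so the knockdown could not be checked and the groups rest on the labels. No coordinates are printed, since the genome build of the probe sets is not given in the sources used here. Values identical to those of an earlier row were found in 170 rows. As a gauge of background, 426 olfactory and vomeronasal receptor genes had a median level of 2.78 and a 95th percentile of 4.22, and 57.8% of probe sets lay above the latter. The number of arrays limits the precision.

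Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), siDicer minus siScr, over all 16383 probe sets. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was the threshold. A second count asked for a fold of at least 1.5 as well. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 26 lists, with the probe set of highest mean level for each gene. The lists, their members and the rule for named genes were fixed before the data were examined. They covered small RNA machinery, melanocyte identity, adhesion, TGF-beta response, cell division and replication, stress, lipid, lysosome, apoptosis and signalling genes, reported microRNA targets and hosts, markers of other cell types, reference genes and 5 classes defined by symbol. The rule named Itgav, Mitf and Dicer1, up to 10 genes with the largest rise and up to 10 with the largest fall past the threshold whose groups did not overlap, and in each list the 3 members with the smallest p. Predicted gene models were left out. Mreg, Lamc1, Fam83d, Cd44, Lama5, Npnt, Pmp2 and single members of lists outside that rule were named after their values were seen.

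Replicate numbers in the labels go with cell passage: number 1 was passage 47, number 2 passage 54 and number 3 passage 56 in both groups. Deviations from the group means correlated between same-numbered arrays across probe sets, with r of 0.44, 0.41 and 0.24, while different numbers gave r from -0.34 to -0.04. Deviations sum to 0 within a group, so values below 0 between different numbers follow on average from the positive ones and add no evidence. Given the shared passages and the same-numbered correlations, the numbers were taken as pairing the samples. The fit reported first does not use this pairing. A fit with replicate number as a block is given where it changed a call or moved a count by more than 1.5 times. The procedure was tested on simulated data over 16383 probe sets. For this comparison the fit without the block recovered 47.8% of simulated changes of 0.5 log2 units, 83.6% of those of 0.75 and 95.5% of those of 1. With the block it recovered 40.3%, 73.1% and 81.8%. The simulated noise was independent between genes and drawn at each probe set's own residual SD in the paired fit. In the real data the block gave the larger count, 163 against 35, so these rates need not hold there. Camera called 0 of 26 lists in simulated data with no shift, where noise was independent between genes. The preset correlation is far below the 0.94 estimated without the block for the cell division list, so camera p-values at the preset are too small for such a list.

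The alternatives were quantile normalization, centring of each array, 2 filters on level, probe sets with 1 symbol, trend and robust eBayes, array weights, a plain equal-variance test, a threshold of 0.1, leaving out each array, other set tests and the mean over probe sets of a gene. Cyclic loess normalization and the removal of identical rows, each with and without the block, were added after the data were seen. A planned search for microRNA seed sites in 3′ UTRs was not run, because 3′ UTR sequences were not used here. Figures were drawn with matplotlib 3.10.9.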

Results

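Dicer cuts microRNA precursors into mature microRNAs. Gene expression was profiled in Melan-a melanocytes 24 hours after transfection with siDicer or siScr, to ask which transcripts differed when Dicer was targeted. Each group held 3 arrays, from cells at passages 47, 54 and 56. Over all probe sets the arrays correlated with r from 0.994 to 0.997 between groups. Dicer1 itself was not analysed here.

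Integrin alpha V, Itgav, was 1.64-fold higher in siDicer than in siScr cells, at 9.87 ± 0.09 against 9.16 ± 0.14 log2 units (SD, n = 3 each). This subunit forms receptors for matrix proteins such as vitronectin. Its log2 change was 0.71 with a standard error of 0.09 (limma, adjusted p = 0.0265), and it was higher in all 3 pairs of the same passage. Among named genes past the threshold without the block, the largest fall was that of Tmem131, a transmembrane protein, which was 1.89-fold lower, at 8.64 ± 0.10 against 9.56 ± 0.02 (adjusted p = 0.00821). Tgfbr1, the type I receptor for TGF-beta, fell by 0.61 ± 0.08 (SE) on the log2 scale, from 7.40 ± 0.07 to 6.79 ± 0.11 (SD, n = 3 each, adjusted p = 0.0265).

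Among named genes past the threshold with groups that did not overlap, 21 rose and 7 fell. The 10 largest rises lay between 0.59 and 0.76 log2 units. Mfsd6, a member of the major facilitator family of transporters, rose from 7.26 ± 0.04 to 8.02 ± 0.16 (SD, n = 3 each). Fndc3b, which carries fibronectin type III domains, rose by 0.74 and Snap23, a SNARE protein of membrane fusion, by 0.71. Ap4b1, the beta subunit of the AP-4 adaptor complex, rose by 0.67, and Fkbp7, a prolyl isomerase of the endoplasmic reticulum, by 0.68. Tiprl, a regulator of PP2A-type phosphatases, and Ttc17 each rose by 0.66. Alg2, a mannosyltransferase of N-glycan synthesis, and Tmco1, a membrane protein of the endoplasmic reticulum, each rose by 0.59. Adjusted p-values of these 10 genes ran from 0.0143 for Snap23 and Ttc17 to 0.044 for Tiprl.

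The falls past the threshold were few. After Tmem131 came Clic4, a chloride intracellular channel protein, which went from 9.57 ± 0.07 to 8.93 ± 0.05 (SD, n = 3 each), a fall by 0.65. Xrn2, the nuclear 5′ to 3′ exoribonuclease, and the palmitoyltransferase Zdhhc21 each fell by 0.60. Aar2, a factor in U5 small nuclear ribonucleoprotein assembly, fell by 0.54, and the deubiquitinase Usp45 by 0.48. Adjusted p-values of these 5 genes lay between 0.0182 and 0.044.

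**Figure D1:**
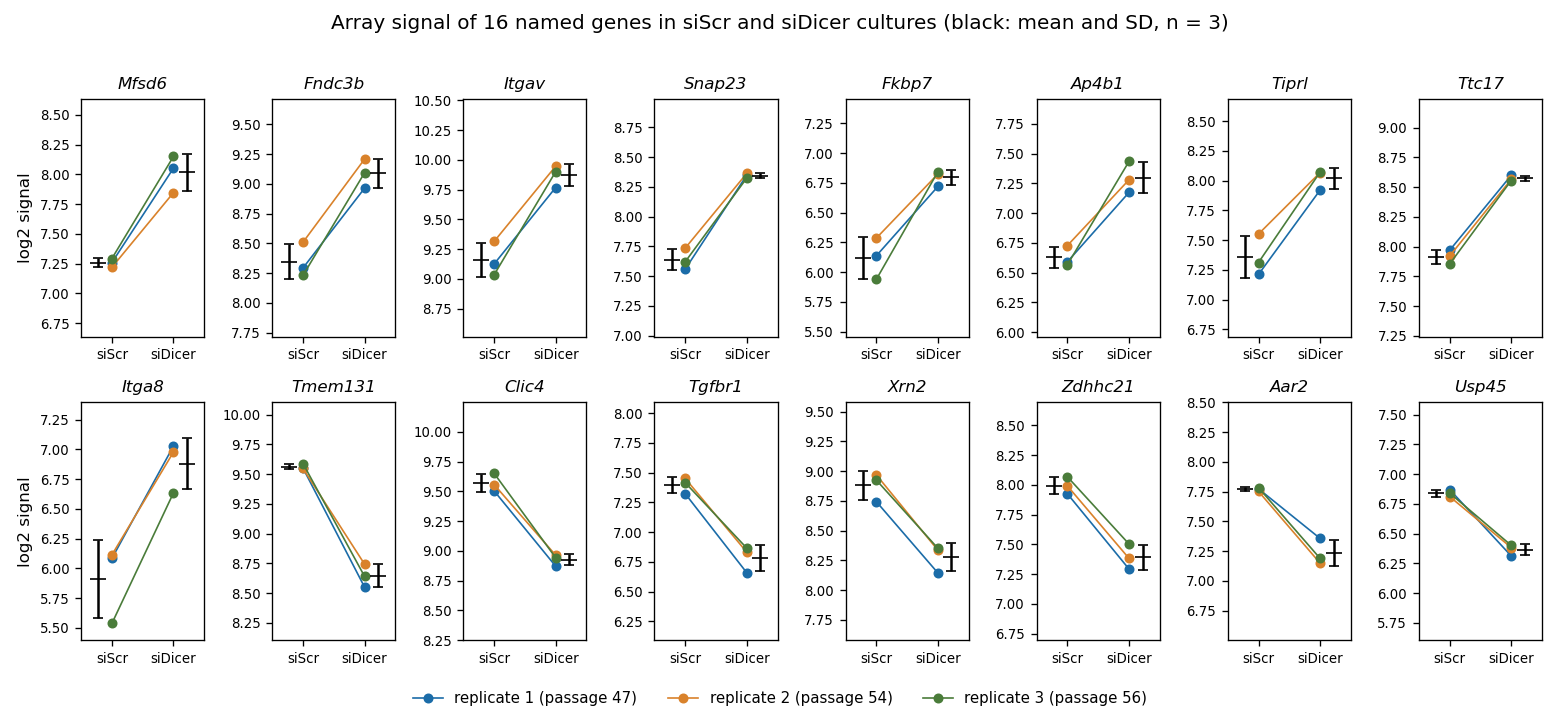
Log2 array signal (vertical axis) of 16 genes in siScr and siDicer cultures, with 1 point per array, lines joining arrays of the same passage, and black marks for the mean and SD of 3 arrays. Itgav lies at 9.16 in siScr and 9.87 in siDicer and Tmem131 at 9.56 and 8.64; Itga8, at 5.91 and 6.88, passed the threshold with the block alone.

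In all, 35 of 16383 probe sets passed the threshold, 24 higher and 11 lower in siDicer (limma), and 29 of them had a gene symbol. At least 1.5-fold changes numbered 19, with 11 higher and 8 lower. With replicate number as a block, 163 probe sets passed, 124 higher and 39 lower, all 35 among them, and 37 of the 163 changed at least 1.5-fold. After quantile normalization the split was 19 higher and 14 lower, and after cyclic loess 19 and 15. Without siDicer replicate 1, siDicer replicate 3 or siScr replicate 3 no probe set passed in limma (1815, 1208 and 1399 at an unadjusted p under 0.05), and 4, 7 and 20 passed without siDicer replicate 2, siScr replicate 1 and siScr replicate 2.

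Of the integrin and focal adhesion list, 7 members were measured: 1 rose, Itgav, and 6 did not pass. Adjusted over the list alone, 2 rose. The other was Itga8, the integrin alpha 8 subunit, at 6.88 ± 0.21 against 5.91 ± 0.32 (SD, n = 3 each). Its log2 change of 0.97 gave an adjusted p of 0.0709 over all probe sets and of 0.0209 with the block. Itga4, Itga6 and Itgb6 had log2 changes of -0.02, -0.12 and -0.07, none past the threshold. Only 6 of the 7 members lay above the receptor background level. The list passed camera upward with a median of 0.08 (adjusted p = 0.0464), but not with the block (adjusted p = 0.0651). With an estimated correlation it did not pass camera either (unadjusted p = 0.0869, adjusted p = 0.888). The adjustment gave many lists this same value of 0.888, here and below, so it does not rank them.

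Genes of cell division were lower in siDicer cells. All 13 measured members had a negative log2 change, with a median of -0.33, and the list passed camera downward (adjusted p = 2.59e-06; with the block, adjusted p = 8.91e-12). With an estimated correlation, without the block, it did not pass camera (unadjusted p = 0.182, adjusted p = 0.888), and that test was not run with the block. In fry, another limma set test, it did not pass either (adjusted p = 0.411), and with the block fry called 0 of 26 lists. The inter-gene correlation was estimated at 0.94 in the fit without the block, so the 13 members were far from independent there. Differences between passages count toward that estimate. Its unadjusted p in limma's camera was 9.95e-08. Another split of the 6 arrays gave a smaller one, 7.29e-16, but with both passage 47 arrays in the same group. The 3 other splits that part every pair gave 0.000581, 0.00488 and 0.388. Each of those 3 swaps the labels of a single pair, so their larger p-values largely follow from the agreement of the pairs. No single member passed without the block, and 4 fell adjusted over the list alone: Aurka, Tpx2, Cenpe and Cdca8. With the block 4 fell over all probe sets, and all 13 adjusted over the list alone. The 4 with the block were Aurka, a mitotic kinase, Tpx2, its activator on the spindle, the kinetochore motor Cenpe and the checkpoint kinase Bub1. With the block they fell by 0.56, 0.54, 0.58 and 0.42, with adjusted p from 0.0234 to 0.0449. In the fit without the block their adjusted p ran from 0.202 to 0.439.

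The DNA replication list did not pass camera (adjusted p = 0.519). Its 6 measured members had a median change of -0.07, and 0 passed without the block. Adjusted over the list alone 1 fell, Ccne2, cyclin E2, with a log2 change of -0.43 and an adjusted p over all probe sets of 0.272 without and 0.0433 with the block. The helicase subunits Mcm3 and Mcm6 had changes of -0.14 and -0.07. Replication-dependent histone genes had a median of -0.12 over 6 members (adjusted p = 0.599). None passed without the block, and with it H2bc18 and H2ac19 fell adjusted over the list alone. The mean change of the cell division list was 0.25 lower than that of the replication list (exact permutation of genes between the lists, p = 0.00147). That test was chosen after the lists were seen and treats genes as independent, which those of cell division were far from, so its p is too small.

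Of 40 genes listed for melanocyte identity and pigmentation, 7 were measured and 0 passed; adjusted over the list alone 1 rose. That gene was Lef1, a transcription factor of the Wnt pathway, at 7.53 ± 0.23 against 7.02 ± 0.17 (SD, n = 3 each), with an adjusted p of 0.212 without and 0.0337 with the block. Tyrp1, a melanin-synthesis enzyme, differed by 0.02 log2 units at a level near 12.8, and the transcription factor Pax3 by 0.00 at 10.6. The melanosome transport gene Mlph differed by -0.12 (adjusted p = 0.727). The list had an adjusted camera p of 0.337. In the neural crest and glial list 0 of 7 passed and 1 rose adjusted over the list alone, Cdh19, a cadherin of the Schwann cell lineage. It had a change of 0.55 and an adjusted p of 0.138 without and 0.0304 with the block.

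Of 13 measured let-7 targets 1 fell, Tgfbr1, and 12 did not pass, with a median of -0.01 and an adjusted camera p of 0.863. With the block Thbs1, described below, rose over all probe sets (adjusted p = 0.0319). Adjusted over the list alone 1 rose and 1 fell, and with the block 2 rose and 1 fell. The rise without the block was Fign, with a change of 0.47 and an adjusted p over all probe sets of 0.167. Of 16 reported targets of other microRNAs 1 rose, Itgav, and 15 did not pass, with a median of 0.03 (adjusted p = 0.337). Adjusted over the list alone 3 rose and 2 fell. Traf6, a signalling adaptor, had a change of 0.37 (adjusted p = 0.0915), Reck, a membrane inhibitor of metalloproteinases, 0.41 (0.202 without and 0.0449 with the block), and Rab22a -0.28 (adjusted p = 0.164).

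No microRNA gene passed among 171 measured, of which 84 lay above the receptor background level. At an unadjusted p under 0.05 in limma, 11 were higher and 5 lower. The smallest p belonged to Mir872, whose change was 0.60 at a level below the background gauge (adjusted p = 0.119). The class had a median of -0.01 and an adjusted camera p of 0.461, and mature microRNAs were not analysed here. In the small RNA machinery list none of the 6 measured genes passed. Its adjusted camera p in limma was 0.863. Ago3, an Argonaute protein, had a change of -0.20 (adjusted p = 0.459) and Ago1 one of -0.05. The microRNA host transcripts had 0 of 5 past the threshold and a median of 0.05 (adjusted p = 0.811).

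The mesenchymal and TGF-beta list had 1 fall, Tgfbr1, among 10 measured genes and did not pass camera (adjusted p = 0.461). Thbs1, thrombospondin 1, a matrix glycoprotein, was at 8.87 ± 0.31 against 8.31 ± 0.40 (SD, n = 3 each), a change of 0.56. It had an adjusted p of 0.429 without and 0.0319 with the block. Id1, an inhibitor of DNA binding that responds to BMP signals, had a change of -0.31 (adjusted p = 0.346). Adjusted over the list alone with the block, Thbs1 and Fn1 rose and Tgfbr1, Id1 and Id3 fell. Of 7 p53 targets 0 passed and 1 fell adjusted over the list alone, Trp53inp1. This stress protein was at 7.21 ± 0.27 against 8.11 ± 0.30 (SD, n = 3 each), a change of -0.90, with an adjusted p of 0.0946 without and 0.0226 with the block. With the block Sesn2 also fell adjusted over the list alone. The p53 list had an adjusted camera p of 0.224.

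**Figure D2:**
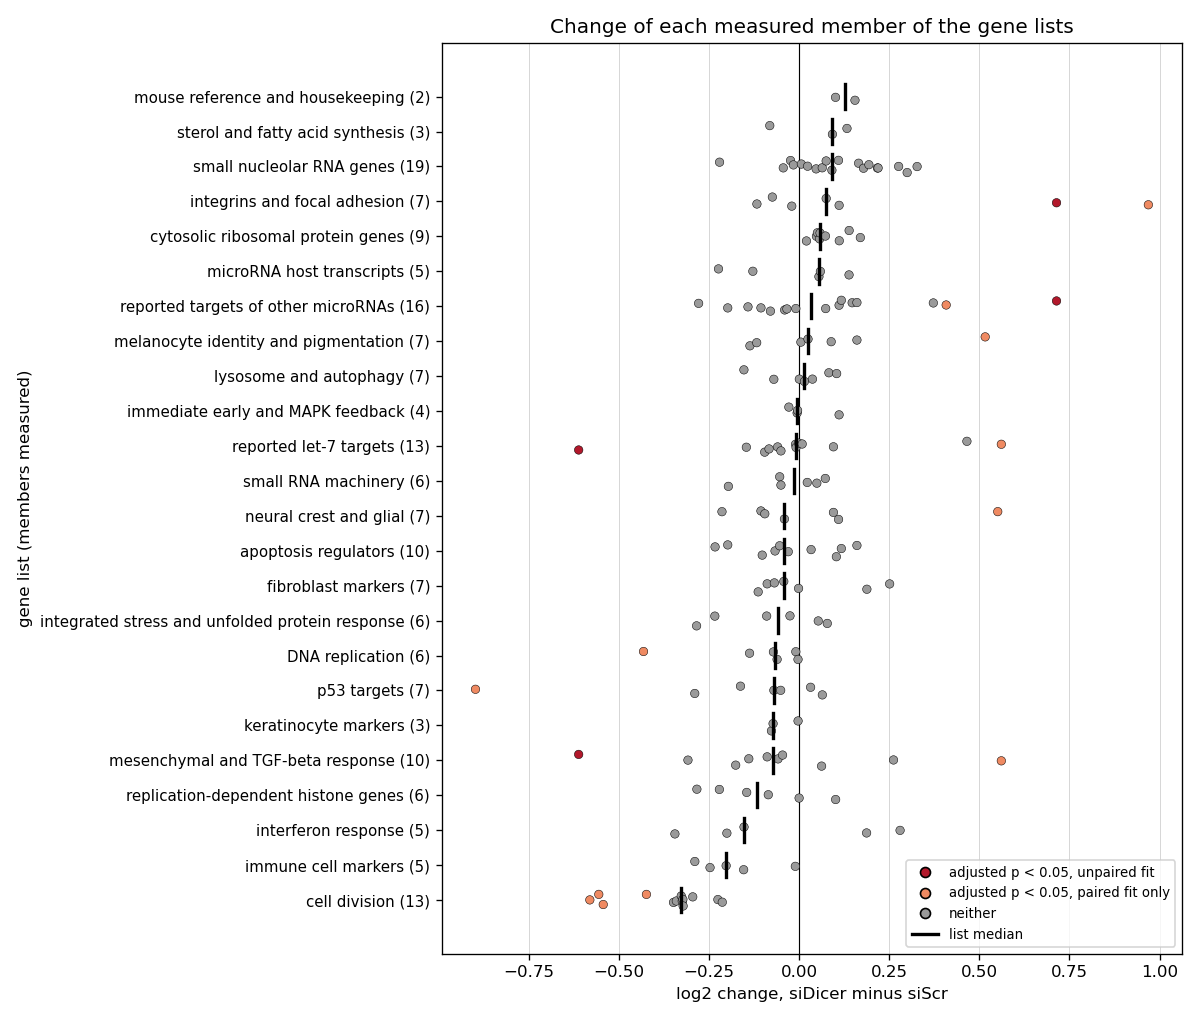
Log2 change, siDicer minus siScr (horizontal axis), of each measured member of the gene lists with members plotted singly, with a black bar for each list's median; red points passed the threshold without the block and orange points with it alone. The 13 cell division genes all lie below 0 around a median of -0.33, while Itgav at 0.71 and Itga8 at 0.97 stand apart from the other integrin list members.

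Markers of other cell types gave few differences. Immune cell markers passed camera downward, with a median of -0.20 over 5 members (adjusted p = 0.0336), but not with the block (0.0651) or an estimated correlation (adjusted p = 0.888). No member passed, and 2 fell adjusted over the list alone. These were the complement gene C1qa, at 5.23 against 5.52, and the Fc receptor chain Fcer1g, at 4.97 against 5.22. Fibroblast markers had 0 of 7 past the threshold, with Col3a1 at 6.09 in both groups and Col5a1 0.19 higher (adjusted p = 0.586). With the block Postn and Col5a1 rose adjusted over the list alone, by 0.25 and 0.19. Keratinocyte markers had 0 of 3, with the largest difference -0.08 for Lor. Their adjusted camera p-values were 0.863 and 0.694.

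Without the block the remaining lists held no gene past the threshold, over all probe sets or adjusted over the list alone. With the block none passed over all probe sets. Adjusted over the list alone, the block gave rises of the interferon response genes Ifih1 and Ddx58. By the same adjustment Gbp2 of that list fell, as did the apoptosis regulators Mcl1 and Cflar and the stress gene Chac1. Cflar had 2 probe sets. The probe set used, that of higher mean level, is numbered on chromosome 3, while the gene table places Cflar on chromosome 1. Its fall may therefore not be that of the gene. Small nucleolar RNA genes passed camera upward with a median of 0.09 over 19 members (adjusted p = 0.0428), but not with the block (0.0503) or an estimated correlation (adjusted p = 0.888). With the block and 1 row kept of identical ones the adjusted p was 0.0486, and the median was -0.04 without siScr replicate 1. All 9 cytosolic ribosomal protein genes were above 0, with a median of 0.06 (adjusted p = 0.0851). That list passed in 3 of 21 alternatives, with an adjusted p as low as 0.000714, and its median ran from 0.02 to 0.15. Its inter-gene correlation was estimated at 0.71, and camera with that estimate gave an adjusted p of 0.888. Interferon response genes had a median of -0.15 over 5 members (adjusted p = 0.863), with Gbp2 at -0.34, but over the alternatives the median ran from -0.23 to 0.18 and so turned in sign. Stress and unfolded protein response genes had a median of -0.06 over 6 (adjusted p = 0.811), apoptosis regulators -0.04 over 10 (0.863) and lysosome and autophagy genes 0.01 over 7 (0.694). Sterol and fatty acid genes had a median of 0.09 over 3 members (adjusted p = 0.613), immediate early genes -0.00 over 4 (0.811), and the reference genes Psmb2 and B2m changes of 0.16 and 0.10 (list adjusted p = 0.337). Olfactory and vomeronasal receptor genes had a median of -0.02 over 426 (adjusted p = 0.694). For the immediate early, neural crest, fibroblast and microRNA gene lists the median was below 0 while camera pointed upward, and for microRNA hosts and let-7 targets the mean and median differed in sign.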

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

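Cyclic loess normalization and the removal of identical rows were chosen after seeing the data. The block, used since passage pairs the arrays, gave 163 changed probe sets (37 at least 1.5-fold) and 1 gene list past the threshold, against 35, 19 and 4 without it. With cyclic loess these were 93, 29 and 1 with the block, and 1 list without it. With 1 row kept of identical ones and the block, 158 probe sets changed, 37 at least 1.5-fold, and 3 lists passed: cell division, small nucleolar RNA and ribosomal protein genes (adjusted p = 0.0486 for the latter pair). Fewer or other probe sets tested gave 59 (level above the median) and 69 (1 symbol). Array weights gave 66 probe sets and 2 lists, a threshold of 0.1 gave 99, and the plain equal-variance test 0, with 1439 at an unadjusted p under 0.05. Lists past the threshold numbered 1 after quantile normalization, 2 after centring, and 0 with an estimated correlation or fry. Leaving out 1 array gave 0 to 20 probe sets, 0 to 18 at least 1.5-fold and 1 to 5 lists. Part of that loss may follow from fewer samples, which was not tested. The small nucleolar RNA median reversed to -0.0445 without siScr replicate 1 (adjusted p = 0.637) and reached 0.203 without siScr replicate 2. The interferon response median, past the threshold nowhere, turned to 0.02 without siDicer replicate 1 and 0.18 without siScr replicate 2. Ribosomal protein genes also passed without either of these arrays. Where no reason is given, the cause was not tested.

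The cell division list stayed past the threshold in every alternative with the preset correlation. It did not pass in camera with an estimated correlation (adjusted p = 0.888) or in fry (adjusted p = 0.411). The plain equal-variance test ended all 17 named rises and falls, Itgav among them. In the 18 other alternatives that refitted it, Itgav kept its direction, with changes from 0.65 to 0.79, and passed in 13; the 5 losses there were leave-one-array-out fits (adjusted p from 0.0125 to 0.158 over all). Of the 17, further losses outside leave-one-array-out fits were Tiprl and Xrn2 after centring, Alg2 after cyclic loess and Aar2 after quantile normalization. The block ended no call among these 17 genes. Dicer1 and the 3′ UTR seed sites gave no value under any setting. Signal over background limits the microRNA genes, since 84 of 171 lay above the receptor level.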

Other observations

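The test of cell division against other splits, the test of microRNA target release and the test of fibroblast-like cells were chosen only after the results were seen. In the paired fit, further genes differed that no list held. Pmp2, the peripheral myelin protein P2, fell by 0.95 log2 units, from 8.40 ± 0.36 to 7.45 ± 0.27 (SD, n = 3 each; limma with the block, adjusted p = 0.0209). Without the block its adjusted p was 0.114. Fam83d, a spindle protein, fell by 0.53 (0.0238 with and 0.127 without the block). Mreg, melanoregulin, a melanosome protein, rose by 0.62 (0.0435 and 0.0877).

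Several genes of the cell surface and matrix rose in the paired fit. Npnt, nephronectin, a matrix ligand of integrin alpha 8, went from 8.59 ± 0.20 to 9.15 ± 0.19 (SD, n = 3 each), with an adjusted p of 0.0232 with and 0.155 without the block. The laminin chains Lamc1 and Lama5 rose by 0.46 and 0.45, and Cd44, a hyaluronan receptor, by 0.38. With the block their adjusted p-values were 0.034, 0.0486 and 0.0486, and without it 0.0773, 0.388 and 0.0944. These genes were picked from the results, so they are no test of a theme.

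The first pattern is the fall of the cell division list. An intensity-dependent shift is argued against by a median of -0.37 after cyclic loess, and a single odd culture pair by medians of -0.47, -0.32 and -0.29 in the pairs of passages 47, 54 and 56, with 13 of 13 members lower in each. A change of mitotic genes in general may account for it: 32 other mitotic genes had a median of -0.18 (limma camera, p adjusted over 2 added lists 0.000229), with 28 below 0, though with an estimated correlation p was 0.399. Of 10 splits of the 6 arrays, 2 gave a list median as far from 0, the real one at 0.33 and the highest other at 0.42, and 10 splits are too few for a share under 0.05. The highest among the 3 other splits that part every pair was 0.16. For the 32 other mitotic genes, splits with both arrays of a passage in the same group gave medians of -0.27, -0.20 and -0.19, beyond the real -0.18. The 3 others that part every pair gave -0.08, -0.10 and 0.02. Each of these 3 splits swaps the labels of a single pair. Their medians nearer to 0, for both sets of genes, largely restate that the pairs agreed and add no further evidence.

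The second pattern is the excess of rises over falls. With the block, 76.1% of 163 calls were rises, and after cyclic loess 66.7% of 93, with a lower 95% binomial limit of 56.1%. That limit treats probe sets as independent, though 6 of the 163 calls had values identical to an earlier row. It is therefore too high, and cannot decide whether an intensity-dependent shift is the whole cause. Without the block the share went from 68.6% to 55.9% after cyclic loess, so part or all of the excess may be such a shift. The share of rises varied when an array was left out, on counts too small to judge whether the excess is stable. Without siDicer replicate 2 the calls were 1 higher and 3 lower, without siScr replicate 1 they were 3 and 4, and without siScr replicate 2 they were 15 and 5. Release of microRNA targets cannot be told apart from no release, since only a fall of the targets would have counted against it. The 16 reported targets of microRNAs other than let-7, Itgav among them, had a median of 0.0323 (limma camera, adjusted p = 0.337). Of them 8 lay above and 8 below 0. The 13 reported let-7 targets had a median of -0.01, with 4 above and 9 below 0 (limma camera, adjusted p = 0.863). Off-target pairing of the siRNA was not tested.

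The third pattern is the rise of Itgav, Itga8 and Npnt. Fibroblast-like cells in the siDicer cultures cannot be told apart by the limits used: of 5 fibroblast markers above the receptor level, 4 had upper 95% limits below the lower limit of 0.51 for Itgav, Col3a1 at 0.20 among them, but that of Postn was 0.61. All these limits came from the fit without the block, which ignores the pairing, and limits with the block were not computed. Postn and Col5a1 rose, by 0.25 and 0.19, adjusted over the list alone with the block. A rise of matrix genes in general cannot be told apart either, since the 37 other matrix genes, with a median of -0.0385 (limma camera, adjusted p = 0.629), left out those that rose with the block. A change in these genes with siDicer may remain, as a hypothesis, and whether it passes through microRNAs was not tested.

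Other splits of the arrays were compared for each count. The real split gave 35 changed probe sets and the highest other 0, so 1 of 10 splits gave as many, and 1 of 10 gave as many as 19 changed at least 1.5-fold, the highest other again giving 0. For gene lists, 6 of 10 splits gave at least the real 4, the highest other giving 10, but each of those 5 others left 2 pairs unparted, and the 3 others that part every pair gave 2, 1 and 2. With 10 splits no share under 0.05 can be reached. Among splits that part all 3 pairs, the block gave 163 probe sets for the real one and 0 for each of the 3 others. Each of those 3 swaps a single pair, so a change shared by all pairs becomes spread there. Their counts thus add little beyond the agreement of the pairs. With fewer than 10 such splits, no share under 0.05 can be reached among them either. Groups did not overlap for 2599 probe sets, 15.9% against 10% by chance for 6 freely exchangeable arrays. Arrays paired by passage are not freely exchangeable, so the 10% is only a rough guide.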
